A study of Mus musculus with 18 samples.

How the data were processed

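RNA of sorted CD4 T cells was measured on 18 Affymetrix M430v2 arrays in 6 groups of 3: Treg (CD25+) and Tconv (CD25-) of lymph node, thymus and epididymal fat. Per the labels, cells were sorted as CD4+ and negative for B220, CD11b and CD8a, with TCRb+ added for fat and a depletion of CD8a cells before the thymus sort. Lymph node and thymus arrays come from pools of 3 to 6 mice and fat arrays from pools of 8 to 10, so an error between replicates measures the spread between pools, not between mice. RNA was amplified in 2 rounds before labelling. Sex is stated for the fat mice only. Il2ra, Cd4, Cd8a, Itgam and Ptprc encode sort markers or their parent protein and are no finding.

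The deposited values are probe set intensity on a linear scale, made by the authors with RMA in GenePattern (version not given). RMA corrects background, quantile-normalizes and summarises probes; which arrays were normalized together is not stated. The medians of the 6 fat arrays (76.9 to 82.2) lie above those of the other 12 (57.9 to 63.0), so the fat columns do not share one scale with the rest, and fat was compared with lymph node on 3 scales: as deposited, after quantile normalization of all 18 arrays, and with each array centred on its median. Changes between fat and lymph node are given relative to the median change of all genes. After quantile normalization that median was -0.01 in Treg and -0.04 in Tconv. For arrays no depth is given; 3 arrays per group limit the precision.

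Of 45101 probe sets, 64 were controls, 34945 carried exactly 1 gene symbol, 932 several and 9211 none in the table used. Each of the 18193 genes with such a probe set was represented by the one with the highest mean over the 18 arrays; other probe sets of a gene can give smaller changes, such as 0.06 for Tnfrsf1b and -0.09 for Ahr in lymph node and 0.32 for Dgat2 in fat. Genes were kept where at least 1 of 6 group means exceeded the median of all values (log2 6.04, intensity 65.9), which left 12821. Genome positions were not used here.

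Log2 intensities were fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with 1 coefficient per group over all 18 arrays (12 residual and 4.83 prior degrees of freedom). The contrasts were Treg against Tconv in each of the 3 tissues, fat against lymph node in Treg and in Tconv, and the Treg effect in fat or in thymus minus that in lymph node. A gene was called, and is said to rise, fall or be higher or lower, at a Benjamini-Hochberg adjusted p under 0.05 over the 12821 genes. In each call between 2 groups that is named, the 3 arrays of one group lay above the 3 of the other, except for Nt5e in fat and Sox4 and Slc4a1 in fat against lymph node Treg. Overlaps of calls between tissues are set beside the overlap of independent lists of the same sizes. All contrasts share one estimate of spread per gene, so the lists are not fully independent and that overlap is no exact level of chance.

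The comparisons, the rule for named genes, 25 gene lists and the alternatives were fixed before the data were examined. Named genes are the 8 largest changes in each direction per contrast among calls whose groups do not overlap, the 3 largest called members in each direction of each list, and 16 genes of prior interest, of which 2 are not reported here. The lists are Treg identity, naive and lymphoid homing, T cell activation and tissue residence, chemokines and chemokine receptors, effector cytokines, cytokine receptors and STAT signalling, lipid uptake, storage and oxidation, sterol synthesis, glycolysis, cell division, immediate early and stress, type I interferon response, helper subset regulators, and adipose Treg genes known from the literature. Lists of markers cover macrophages and monocytes, dendritic cells and MHC class II, adipocytes, stromal, endothelial and mesothelial cells, B cells, NK and cytotoxic cells, mast cells and granulocytes, immature thymocytes, red cells, sex-linked genes and reference genes. Of 515 list genes 471 were matched to a probe set and 44 were not analysed here. Lists share members. The adipose Treg list, partly chosen in the literature on these arrays, has members in the activation, chemokine, lipid and helper subset lists. It also has members in the effector cytokine, cytokine receptor and Treg identity lists, so tests of these lists in fat are not independent of it. Each list was tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast; red cell transcripts, with 2 measured members, had no camera test. Camera compares a list with all other genes, so its direction allows for the shift between fat and lymph node. With the replicate block and the other alternatives, camera was run at the preset correlation only. Counts of called members are given over all genes and adjusted over the list alone.

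Treg and Tconv arrays of the same replicate number varied together within a tissue. Deviations from the group mean correlated across genes at 0.351 to 0.678 in the 9 pairs of the same number, each above 0.1. Each of these pairs also shares an array run, as given below, so a shared pool and a shared run cannot be told apart. Between fat and lymph node, arrays of the same number correlated at -0.165, 0.0970 and -0.255 in Treg and -0.504, -0.0478 and -0.363 in Tconv, so they are not pairs. Genes are not independent replicates, and no p is taken from these correlations. Counts with replicate number as a block stand beside the main counts. Array numbers in the labels fall into 5 runs of neighbours, taken as array runs since no scan date is given: run 1 holds thymus replicate 1, run 2 thymus replicate 2, run 3 fat replicate 3, lymph node replicate 1 and thymus replicate 3, run 4 fat and lymph node replicate 2, and run 5 fat replicate 1 and lymph node replicate 3. Arrays of a run correlated at 0.341 (limma duplicateCorrelation, with statmod 1.5.0), and list medians within runs are given beside the pooled ones. Deviations of fat and lymph node arrays of runs 5, 4 and 3 correlated at 0.134, 0.0970 and 0.407 in Treg. In Tconv these values were 0.476, -0.0478 and 0.423.

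Each alternative was run on its own against the fit above: replicate or array run as a block, only the compared groups in the fit, the 3 scales, no or a stricter (60th percentile) filter, log2 of the value plus 16, the mean of probe sets or every probe set, eBayes with trend and robust together, array weights, a 2-fold limit, a 2-fold difference of averages of linear values in place of the test, and each array left out in turn. A count of genes passing on all 3 scales and a fit without the fat arrays of run 5 were added after seeing the data. The fit was tested on simulated data of 12821 genes with 200 changed: at a log2 change of 2 it recovered 97% to 100% in the comparisons of 2 groups and 87% to 88% in the differences of effects, at a change of 1 it recovered 74% to 86% and 40% to 45%, and it made 5 to 17 false calls. Camera found 100% of lists of 20 genes raised by 0.5 and 1% of unchanged ones. The simulated noise was independent between genes and between arrays. These rates therefore do not carry over to lists of correlated genes or to arrays that vary together. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.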

Results

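Transcripts of CD4 T cells from mouse lymph nodes, thymus and epididymal abdominal fat were measured on 18 Affymetrix M430v2 arrays. In each tissue, CD25+ cells (here Treg) and CD25- cells (here Tconv) were sorted from pools of mice and hybridised as 3 arrays each, which gave 6 groups. The fat cells came from male C57BL/6 mice of 25 to 35 weeks, the lymph node cells from C57BL/6 mice of 32 to 36 weeks, and the thymus cells from BDC2.5/NOD mice of 4 to 6 weeks. The median intensity of an array lay between 57.9 and 63.0 in the 12 lymph node and thymus arrays and between 76.9 and 82.2 in the 6 fat arrays. Of 18193 genes with a probe set, 12821 passed the filter on dim signals and were tested. The first principal component carried 54.0% of the variance and parted fat from the other tissues; the second carried 13.7% and parted thymus from lymph node.

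**Figure D1:**
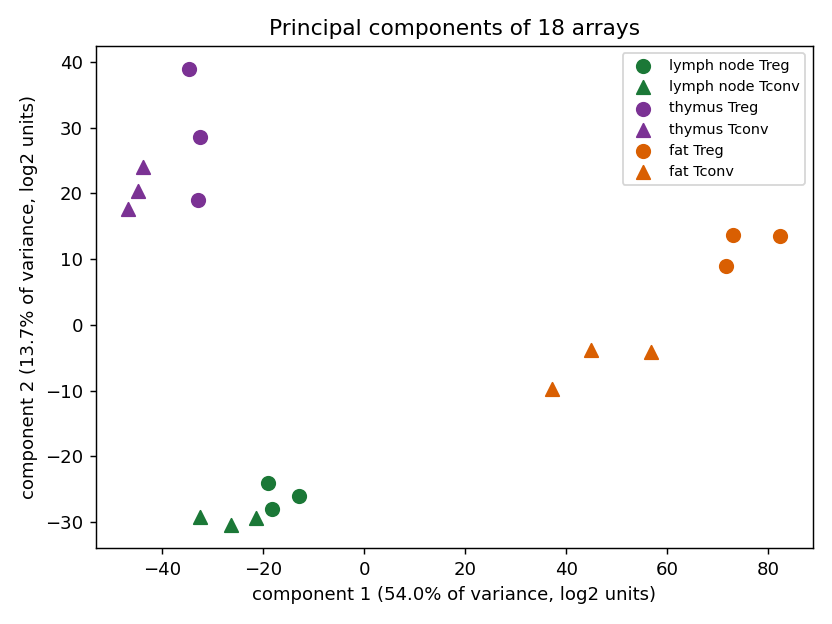
Principal components of the 18 arrays (log2 intensity of 12821 genes; both axes in log2 units); each point is 1 array, coloured by tissue, circles for Treg and triangles for Tconv. Component 1, with 54.0% of the variance, separates the fat arrays from the rest, and component 2 the thymus from the lymph node arrays.

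The first comparison asks which transcripts distinguish CD25+ from CD25- CD4 T cells of lymph nodes. Treg carried the transcripts by which regulatory T cells are known. Foxp3, the transcription factor of the lineage, had an intensity of 901 ± 55.8 (SD, n = 3 arrays) in Treg and 44.4 ± 8.8 in Tconv, a 20.6-fold difference (adjusted p = 3.03e-08). The inhibitory receptor gene Ctla4 was higher by 3.34 ± 0.32 (log2 fold change ± SE; brackets with a single value give the log2 fold change), and so were Ikzf2 (2.12 ± 0.28), which encodes Helios, Tnfrsf18 (1.43 ± 0.21), which encodes GITR, Klrg1 (4.29 ± 0.20) and the integrin gene Itgae (4.14 ± 0.22). Il10, an anti-inflammatory cytokine gene, was higher by 1.26 ± 0.17. Among the transcripts lower in Treg were Pde3b (-3.90 ± 0.24), a phosphodiesterase gene, Il21 (-3.07 ± 0.44), a cytokine gene of helper cells, Dapl1 (-3.25 ± 0.43) and Vipr1 (-2.86 ± 0.25).

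All 25 of 25 measured genes of the Treg identity list rose in lymph node Treg, and 25 did when adjusted over the list alone (median 2.59; camera adjusted p = 3.7e-73). Il2ra (5.28 ± 0.30) encodes CD25, by which the cells were sorted. Of the T cell activation and tissue residence list, 11 of 26 rose, with 12 adjusted over the list alone (adjusted p = 1.78e-15). The largest rises there were Rgs1 (3.15), Alcam (2.32) and Tnfrsf1b (1.89). Cytokine receptors and STAT signalling genes rose in 8 of 26 cases, 9 higher and 1 lower adjusted over the list alone (adjusted p = 9.25e-07). They included Socs2 (4.24), Il2rb (2.56) and Il1r2 (2.52), a decoy receptor for interleukin-1. In the helper subset regulators, 6 of 14 rose and 1 fell, with 6 and 1 adjusted over the list alone (adjusted p = 9.25e-07). Ahr (3.11), Irf4 (1.87) and Prdm1 (1.47) were higher and Eomes (-1.14) was lower. The naive and lymphoid homing list went the other way: 4 of 14 members fell, 6 adjusted over the list alone (adjusted p = 1.36e-06), including Igfbp4 (-1.98), Satb1 (-1.29) and Lef1 (-1.32). Of the chemokines and their receptors, 4 of 30 rose, 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0253, but 0.522 with an estimated correlation), among them Ccr6 (2.83), Cxcl2 (1.78) and Ccr2 (1.97, and 0.13 to 0.89 on 3 other probe sets). Cxcl2 lay below the dim filter in both lymph node groups (57.9 in Treg and 16.8 in Tconv), so the size of its change is approximate. The camera calls of the other lists of this paragraph held with an estimated correlation (adjusted p from 7.3e-05 for Treg identity to 0.0475 for naive and lymphoid homing). Cd4 (-0.74 ± 0.21, adjusted p = 0.0642, but 0.00916 with the replicate block) and Pparg (-0.15 ± 0.24, adjusted p = 0.954) did not pass the test.

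Other lists moved in lymph node Treg as well. The adipose Treg list, partly chosen on these arrays, rose in 12 of 21 genes, 12 adjusted over the list alone (adjusted p = 1.69e-22, and 0.000131 with an estimated correlation), with Gzmb (2.80) and Tnfrsf4 (2.59) beside Klrg1. Of the markers of NK cells and cytotoxic cells, 1 was higher and 2 were lower of 12, 1 and 4 adjusted over the list alone (adjusted p = 0.00431, and 0.0328 with an estimated correlation): Nkg7 (0.96), Klrd1 (-2.65) and Eomes. Immediate early and stress genes rose in 3 of 30 cases, 5 adjusted over the list alone (adjusted p = 4.85e-05, but 0.136 with an estimated correlation), and glycolysis genes in 2 of 12, 2 adjusted over the list alone (adjusted p = 0.0157, but 0.136 with an estimated correlation). Cell division genes had a median of 0.30 (adjusted p = 0.0193, but 0.761 with an estimated correlation). Of the B cell markers, Bank1 (1.35 ± 0.19) and Cd79b (1.02 ± 0.26) were higher in Treg, 2 of 10 and as many adjusted over the list alone (adjusted p = 0.304).

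In lymph nodes 554 genes passed the test, 412 higher and 142 lower in Treg, of which 329 differed at least 2-fold. Groups of 3 arrays that did not overlap were found for 16.5% of genes, where chance gives 10% for arrays that vary independently. Treg and Tconv arrays of a number varied together, so the 10% is approximate here and in the other tissues. With replicate number as a block 1028 genes passed (718 higher, 310 lower). Within array runs 3, 4 and 5, each with 1 pair of arrays, the median of the Treg identity list was 2.95, 2.64 and 2.46 and that of the naive list -0.73, -0.61 and -0.52.

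The same question was put to CD4 T cells of the thymus. There Foxp3 measured 774 ± 234 in Treg and 32.6 ± 10.1 in Tconv (SD, n = 3), and Ctla4 was 23.7-fold higher in Treg. The calcium-binding protein gene S100a6 (5.01 ± 0.34), the integrin gene Itgb8 (4.89 ± 0.37), Klrg1 (4.71 ± 0.20) and the cytokine signalling inhibitor Socs2 (4.62 ± 0.25) were among the transcripts with the largest rise. The chemokine receptor genes Ccr6 (3.92 ± 0.23), Cxcr6 (2.67 ± 0.37) and Cxcr3 (2.25 ± 0.21) were higher as well, while Ccr7 measured 584 ± 202 in Treg and 1040 ± 390 in Tconv (adjusted p = 0.267). Of the chemokines and their receptors, 4 of 30 rose and 0 fell, 4 and 1 adjusted over the list alone (adjusted p = 0.0524). Lower in thymic Treg were Cnga1 (-2.54 ± 0.21), Itgb3 (-2.46 ± 0.20), Pde3b (-2.28 ± 0.24) and the kinase gene Sgk1 (-2.08 ± 0.35). Il10 did not pass the test (0.13 ± 0.17, adjusted p = 0.824).

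Of the Treg identity list, 24 of 25 genes rose in the thymus and 25 did adjusted over the list alone (median 2.53; adjusted p = 1.02e-61). T cell activation and tissue residence genes rose in 13 of 26 cases, 17 adjusted over the list alone (adjusted p = 8.08e-18), with Rgs1 (4.07), Il18r1 (3.18) and Cxcr6 (2.67) ahead. The cytokine receptor list had 10 higher and 1 lower of 26, and 11 and 1 adjusted over the list alone (adjusted p = 1.78e-09). Tgfbr2, a receptor for TGF-beta, was the lower one (-0.91). Helper subset regulators rose in 6 of 14 cases, 8 adjusted over the list alone (adjusted p = 9.74e-09), among them Ahr (3.01), Maf (2.60) and Eomes (1.83). These calls held with an estimated correlation (adjusted p from 0.000172 to 0.00427). In the glycolysis list 3 of 12 rose, 3 adjusted over the list alone: Tpi1 (1.54), Hk2 (1.10) and Pgam1 (0.88) (adjusted p = 0.000493, and 0.0445 with an estimated correlation). Sterol synthesis genes rose in 2 of 16 cases, Sqle (1.09) and Insig1 (1.00), with 3 adjusted over the list alone (adjusted p = 0.000265, but 0.102 with an estimated correlation). Of the effector cytokines 4 rose and 1 fell of 19, with 5 and 1 adjusted over the list alone (adjusted p = 0.0323, but 0.192 with an estimated correlation and 0.0687 with the replicate block). Penk (2.99), Tnfsf11 (1.34) and Lta (1.26) were higher and Il21 (-1.93) lower. The adipose Treg list rose in 7 of 21 genes, 11 adjusted over the list alone (adjusted p = 3.51e-10, and 0.00292 with an estimated correlation). Immediate early and stress genes split into 7 higher and 3 lower of 30, 11 and 4 adjusted over the list alone (adjusted p = 0.0074, but 0.352 with an estimated correlation), with Jun (2.18) higher and Egr1 (-0.94) lower. The naive and lymphoid homing list had a median of -0.34 (adjusted p = 0.0074, but 0.31 with an estimated correlation).

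In the thymus 638 genes passed the test, 411 higher and 227 lower in Treg, and 340 differed at least 2-fold. Groups did not overlap for 19.3% of genes, where chance gives 10% for arrays that vary independently. With the replicate block 1528 genes passed (834 higher, 694 lower), without Treg replicate 3 it was 976, and with only the 6 thymus arrays in the fit 383. The median of the Treg identity list was 2.66, 2.15 and 2.62 within runs 1, 2 and 3, and that of the cell division list, which changed sign, was 0.85, 0.77 and -0.74 (adjusted p = 0.0245, but 0.776 with an estimated correlation).

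The comparison of Treg with Tconv was then made in fat. Il10 measured 6120 ± 505 in fat Treg and 221 ± 34.1 in fat Tconv (SD, n = 3), a 27.9-fold difference (adjusted p = 4.22e-12). Pparg, a nuclear receptor known as a regulator of fat cell genes, measured 858 ± 174 against 89.9 ± 35.3, and the chemokine receptor gene Ccr1 663 ± 161 against 31.1 ± 6.32. Ifng, the gene of interferon gamma, was lower in Treg, at 575 ± 523 against 13800 ± 785, and so was Tbx21, which encodes the type 1 regulator T-bet, at 57.3 ± 20.8 against 1360 ± 460. Foxp3 was 18.1-fold higher in fat Treg.

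The chemokine genes Cxcl3 (7.28 ± 0.18) and Cxcl2 (3.69 ± 0.22) were higher in fat Treg, as were AA467197 (5.67 ± 0.26), Hpgd (4.63 ± 0.29), which encodes an enzyme that degrades prostaglandins, and Gata3 (2.79 ± 0.22), the type 2 regulator. Of the 21 measured adipose Treg genes known from the literature, 19 rose, and 20 did adjusted over the list alone (median 2.55; adjusted p = 1.64e-34, and 2.65e-05 with an estimated correlation). Part of that list was chosen on these arrays, so its direction is no independent evidence. Members such as Alcam, Dgat1, Gata3 and Pparg also belong to the activation, lipid or helper subset lists, which are thus not independent of it. The Treg identity list rose in 16 of 25 genes and fell in 1, with 16 and 1 adjusted over the list alone (adjusted p = 4.97e-16, and 0.0169 with an estimated correlation). The gene that fell was Nt5e (-1.02 on the probe set used, 0.01 and 0.02 on 2 others), which encodes CD73. Cytokine receptor genes rose in 6 and fell in 2 of 26 cases, 6 and 3 adjusted over the list alone (adjusted p = 0.0293, but 0.259 with an estimated correlation and 0.0634 with the replicate block). Il10ra (3.15) and Il1r2 (2.25) were higher and Socs3 (-1.76) was lower. Lipid uptake, storage and oxidation genes rose in 5 and fell in 1 of 30, 6 and 1 adjusted over the list alone (adjusted p = 0.0168, but 0.341 with an estimated correlation). Those that rose most were Pparg and the triglyceride synthesis genes Dgat2 (3.13) and Dgat1 (2.13), and Scd2 fell (-0.84). T cell activation and tissue residence genes were 15 higher and 4 lower of 26, 18 and 4 adjusted over the list alone (adjusted p = 8.17e-08, and 0.00916 with an estimated correlation), with Alcam (3.04) and Pdcd1 (2.91) higher and Itgb1 (-3.10) lower. Immediate early and stress genes were 10 higher and 3 lower of 30, 11 and 4 adjusted over the list alone (median 0.33; adjusted p = 0.00455, but 0.372 with an estimated correlation). Atf3 measured 2370 ± 115 in fat Treg and 301 ± 37.4 in fat Tconv, Fosb 6940 ± 1100 against 2030 ± 323 and Gadd45b 11400 ± 4120 against 3220 ± 1340 (SD, n = 3), while Hspa1a was lower in Treg, at 1960 ± 744 against 4540 ± 1510. Of the immature thymocyte markers, 1 was higher and 3 were lower of 14, the same adjusted over the list alone (adjusted p = 0.04, but 0.318 with an estimated correlation and 0.0702 with the replicate block).

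On the Tconv side of fat lay Fasl (-5.11 ± 0.18), Ifng (-5.02 ± 0.48), Tbx21 (-4.57 ± 0.28), the chemokine gene Ccl5 (-4.25 ± 0.25), Cxcr3 (-4.01 ± 0.21), a chemokine receptor gene of type 1 cells, and the cytotoxic granule gene Nkg7 (-3.30 ± 0.21). Of the markers of NK cells and cytotoxic cells, 5 of 12 fell in Treg, 5 adjusted over the list alone (adjusted p = 0.000143, and 0.0123 with an estimated correlation). Effector cytokines split, with 5 higher and 5 lower of 19, 7 and 5 adjusted over the list alone (adjusted p = 0.761). Il5 (2.82-fold) and Penk (3.47-fold) rose beside Il10. Helper subset regulators split too, 5 higher and 2 lower of 14, 5 and 2 adjusted over the list alone (adjusted p = 0.192), with Gata3, Irf4 (2.40) and Rora (1.60) on the Treg side and Tbx21 and Eomes (-3.33) on the Tconv side. Bcl2, which opposes cell death, was lower in Treg on the probe set used (-3.81 ± 0.34), while its 4 other probe sets gave values from -3.37 to -0.84. The naive and lymphoid homing list fell in 8 of 14 genes, 1 higher and 10 lower adjusted over the list alone (adjusted p = 7.99e-08, and 0.0342 with an estimated correlation), such as Bach2 (-3.27), Satb1 (-3.01) and Ccr7 (-1.74). Cell division genes fell in 5 of 27 cases, 5 adjusted over the list alone, such as Top2a (-1.47) and Mki67 (-1.36) (adjusted p = 8.42e-05, but 0.538 with an estimated correlation). Type I interferon response genes fell in 6 and rose in 1 of 21, 7 and 1 adjusted over the list alone, with Ifit2 (-1.91), Ifit1 (-1.44) and Rtp4 (-1.42) lower and Isg20 (1.08) higher (adjusted p = 0.000143, but 0.406 with an estimated correlation).

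In fat 1476 genes passed the test, 810 higher and 666 lower in Treg, and 748 differed at least 2-fold. Groups did not overlap for 25.2% of genes, where chance gives 10% for arrays that vary independently. Markers of macrophages and monocytes had a median of 0.40 between the 2 fat groups (1 of 19 higher, 2 lower; adjusted p = 0.0689, but 0.00169 with the replicate block), and markers of adipocytes 0.17 (1 of 8 higher; adjusted p = 0.482). With the replicate block 2652 genes passed (1311 higher, 1341 lower). Within runs 3, 4 and 5 the median of the adipose Treg list was 2.42, 2.54 and 2.67, that of Treg identity 2.04, 1.52 and 2.12 and that of the naive list -1.56, -1.62 and -0.60.

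**Figure D2:**
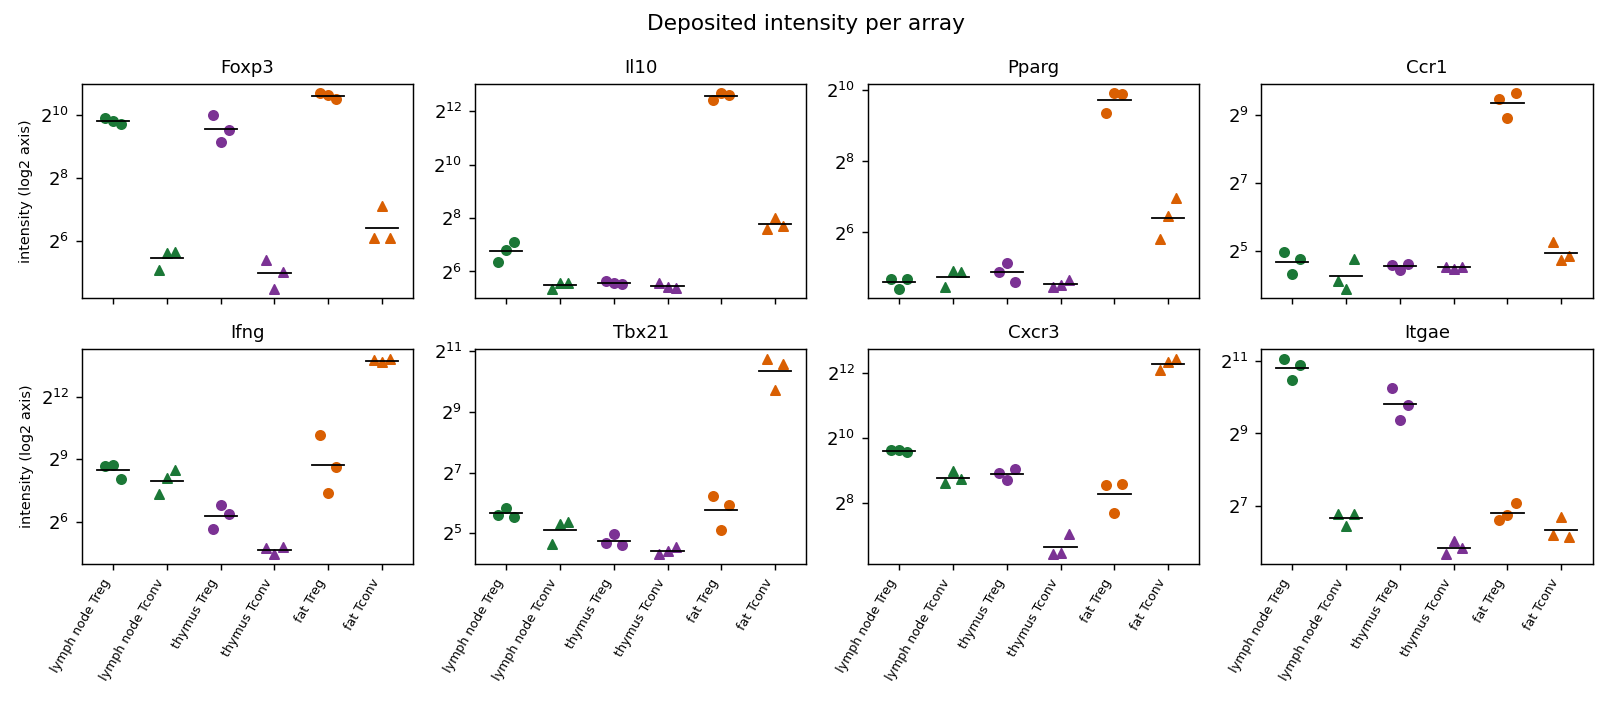
Intensity per array (log2 axis) of Foxp3, Il10, Pparg, Ccr1, Ifng, Tbx21, Cxcr3 and Itgae in the 6 groups; points are arrays (n = 3 per group) and the black line is the geometric mean. Il10, Pparg and Ccr1 are highest in fat Treg, and Ifng, Tbx21 and Cxcr3 in fat Tconv.

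The 3 tissues share no arrays, and their lists of called genes were set side by side. The fit gives each gene one spread for all tissues, so a gene with a small spread is favoured in every list. The values for independent lists are therefore a guide and no exact level of chance. In Treg of all 3 tissues 107 genes were higher and 41 lower, where independent lists would give 0.834 and 0.131. Foxp3, Ctla4, Ikzf2, Tnfrsf18, Klrg1, Itgb8, Il1r2, Penk and Tnfrsf4, which encodes OX40, were among those higher throughout, and Pde3b, Il21, Themis, Lypd6b, Tdrp and Il1rl2 among those lower. Lymph node and thymus shared 224 higher and 76 lower genes (13.2 and 2.51 for independent lists), with 1 gene lower in lymph node Treg and higher in thymic Treg. Lymph node and fat shared 178 and 69 (26 and 7.38), and thymus and fat 153 and 83 (26 and 11.8). Of the genes higher in lymph node Treg, 24 were lower in fat Treg than in fat Tconv, and 7 went from lower to higher; for thymus and fat these counts were 30 and 19. Genes are not independent, so no p is taken from these counts. With the replicate block the sums of both directions rose from 300 to 584 for lymph node and thymus, from 247 to 470 for lymph node and fat, and from 148 to 299 for the 3 tissues.

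Fat Treg were then compared with lymph node Treg, to ask what sets the Treg of fat apart. The fat arrays had higher values on the whole: the median log2 change of all genes was 0.365 in Treg and 0.333 in Tconv, and changes are given relative to this shift, with the SE of the unshifted change. Counts of called list members are as deposited unless stated otherwise. On that scale 5838 of all 12821 genes passed as higher in fat Treg and 1180 as lower, and 4899 and 526 in fat Tconv. A list count near this share of all genes is no effect of the list. Fat Treg carried Il10 at 6120 ± 505 against 111 ± 27.9 in lymph node Treg (SD, n = 3), a relative change of 5.45 ± 0.17 (adjusted p = 8.66e-14), Pparg at 858 ± 174 against 24.4 ± 2.57, and Klrg1 at 11000 ± 77.1 against 2460 ± 688. The chemokine genes Cxcl3 (7.44 ± 0.18) and Cxcl2 (7.35 ± 0.22), the chemokine receptor genes Ccr1 (4.30 ± 0.23) and Ccr2 (3.40 ± 0.33), and Gata3 (3.21 ± 0.22) were higher as well. Itgae, which encodes the integrin CD103, fell from 1820 ± 357 in lymph node Treg to 114 ± 19.2 in fat Treg, and Bach2 (-4.38 ± 0.26), Gpr83 (-3.83 ± 0.37) and Ccr7 (-2.65 ± 0.36) were lower too. The rise of Foxp3 (0.79 as deposited, 0.42 relative) did not pass the test after quantile normalization of all arrays (adjusted p = 0.23).

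The adipose Treg list rose in 20 of 21 genes, 20 adjusted over the list alone (median relative change 2.94; adjusted p = 6.5e-12, and 0.00492 with an estimated correlation), on a list partly chosen on these arrays. T cell activation and tissue residence genes rose in 22 of 26 cases and fell in 1, with the same counts adjusted over the list alone (median 1.45; adjusted p = 2.62e-07, and 0.0121 with an estimated correlation). Dgat1 (4.07), which is also in the adipose Treg list, and Rora (3.53) are examples. In the naive and lymphoid homing list 10 of 14 fell and 1 rose, the same adjusted over the list alone (median -1.42; adjusted p = 9.05e-09, and 0.0294 with an estimated correlation), with Bach2, Ccr7 and Satb1 (-3.21) lower. Chemokines and their receptors rose in 24 and fell in 4 of 30, 25 and 4 adjusted over the list alone, and 16 rose with quantile normalization (adjusted p = 0.00377, but 0.286 with an estimated correlation). Sterol synthesis genes rose in 12 of 16 cases, 13 adjusted over the list alone and 8 with quantile normalization, among them Insig1 (2.05) and Cyp51 (1.64) (adjusted p = 0.017, but 0.286 with an estimated correlation). The type I interferon list had 9 lower and 1 higher of 21, 8 and 1 adjusted over the list alone, and 10 lower with quantile normalization, Usp18 (-3.59), Ifit2 (-2.77) and Rtp4 (-2.69) among them (adjusted p = 1.01e-05, but 0.286 with an estimated correlation). In the lipid list 17 of 30 rose and 5 fell, 18 and 5 adjusted over the list alone (adjusted p = 0.0569), where 5838 of all 12821 genes rose as deposited. Fabp4 (7.98), Lpl (4.88) and Pparg were higher, and Abca1 (-2.23), a cholesterol exporter, was lower. Bcl2 was lower on the probe set used (-4.79 ± 0.34 as deposited), while 1 of its 5 probe sets gave 0.24 as deposited, under the shift of 0.365. Cell division genes were 3 higher and 1 lower of 27, 1 and 1 adjusted over the list alone (adjusted p = 0.0258, but 0.644 with an estimated correlation), and immature thymocyte markers 3 higher and 4 lower of 14, 3 and 4 adjusted over the list alone (adjusted p = 0.034, but 0.286 with an estimated correlation). In both lists a smaller share of members rose than of all genes (5838 of 12821), so these counts are no rise of the lists.

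Transcripts of other cells of fat tissue were also higher in fat Treg. Counts of these markers, here and in Tconv, cover only members above the dim filter. A marker dim elsewhere can pass that filter through the fat groups alone, so the counts favour markers that rose. Of the markers of stromal, endothelial and mesothelial cells, 10 of 11 rose (11 adjusted over the list alone; median 2.20), such as Dcn (5.37) and Col3a1 (4.47), and 10 rose and 1 fell with quantile normalization (adjusted p = 6.26e-05, but 0.286 with an estimated correlation). Macrophage and monocyte markers rose in 15 and fell in 1 of 19, the same adjusted over the list alone and 13 and 2 with quantile normalization (median 1.39; adjusted p = 0.0072, but 0.555 with an estimated correlation). Lgals3 (4.33), Cd163 (4.07) and C1qb (3.30) rose. Adipocyte markers rose in 7 of 8 cases (7 adjusted over the list alone), 4 with quantile normalization (adjusted p = 0.00478, but 0.286 with an estimated correlation). Fabp4 measured 2530 ± 437, Lpl 1790 ± 1210 and Car3 331 ± 330 in fat Treg (SD, n = 3), against 7.73, 37.9 and 16.2 in lymph node Treg. Markers of dendritic cells and MHC class II rose in 7 and fell in 1 of 10, 7 and 1 adjusted over the list alone and 3 and 1 with quantile normalization (adjusted p = 0.232). B cell markers rose in 6 and fell in 3 of 10 (6 and 3 adjusted over the list alone; adjusted p = 0.435). Markers of mast cells and granulocytes rose in 6 of 7 (6 adjusted over the list alone; adjusted p = 0.479), while quantile normalization put 1 lower and none higher. Immediate early and stress genes, which respond to handling of cells as well as to activation, rose in 26 of 30 cases and fell in 1, the same adjusted over the list alone, and 22 rose with quantile normalization (median 2.83; adjusted p = 2.99e-11, and 0.0294 with an estimated correlation). Hspa1a, a heat shock gene, measured 1960 ± 744 against 11.7, and Fosb (6.78) and Klf4 (6.27) rose; Egr2 (-2.70) fell. The log2 ratio of the 3' to the 5' Gapdh control was 3.32 ± 0.27 in fat Treg and 3.51 ± 0.35 in fat Tconv, against 3.01 ± 0.61 and 3.04 ± 0.46 in lymph node (SD, n = 3), and that of the actin control 1.31 ± 0.34 and 1.45 ± 0.41, against 1.42 ± 0.46 and 1.33 ± 0.32.

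Of all genes, 7018 passed the test as deposited, 5838 higher and 1180 lower in fat Treg. With quantile normalization 1969 were higher and 2360 lower, and 1641 and 1178 passed in 1 direction under the deposited, quantile and centred scales, 723 and 470 of them at least 2-fold. With replicate number as a block 7103 passed. Within runs 3, 4 and 5 the median relative change was 3.05, 2.66 and 2.87 for the adipose Treg list, -1.72, -1.79 and -1.32 for the naive list, 2.93, 2.95 and 2.44 for the stress list, 2.12, 1.60 and 2.56 for stromal markers and 1.83, 0.64 and 1.52 for macrophage markers.

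**Figure D3:**
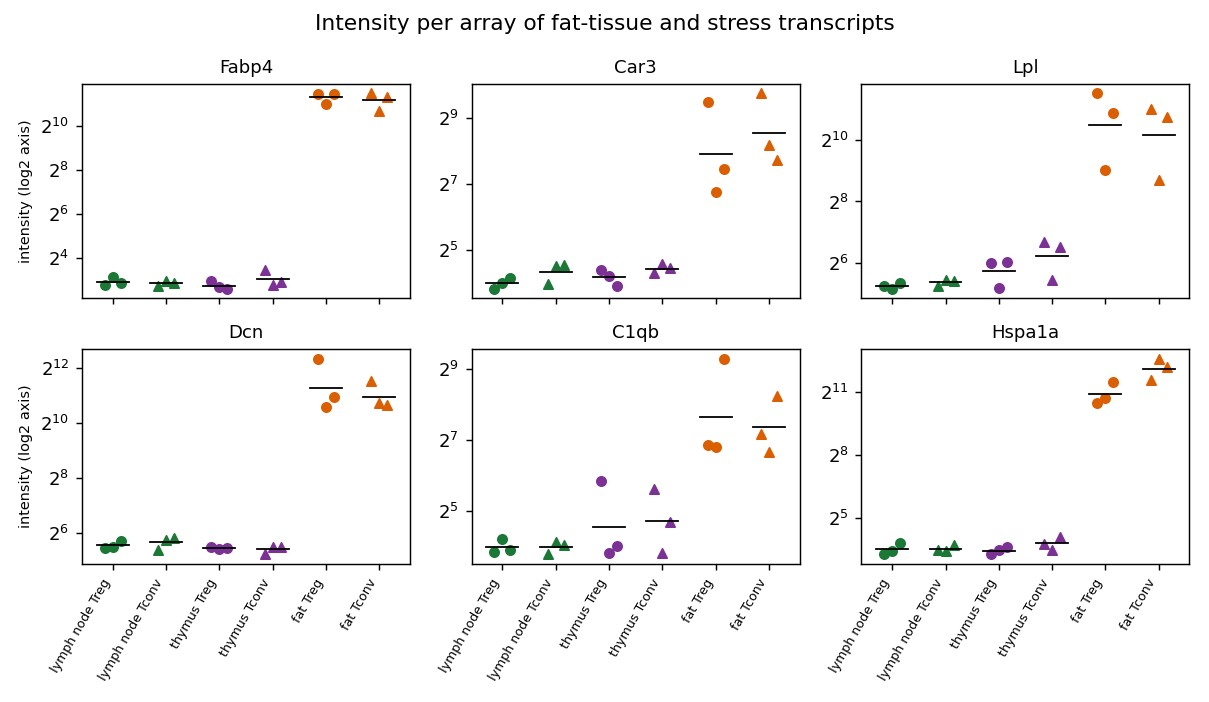
Intensity per array (log2 axis) of Fabp4, Car3, Lpl, Dcn, C1qb and Hspa1a in the 6 groups; points are arrays (n = 3 per group) and the black line is the geometric mean. All 6 transcripts are higher in both fat groups than in lymph node, and Car3 and Lpl vary more between fat arrays than Fabp4.

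The same tissue comparison in Tconv asked what fat shares between both cell types. Ifng measured 13800 ± 785 in fat Tconv and 264 ± 99 in lymph node Tconv (SD, n = 3), a relative change of 5.45 ± 0.48 (adjusted p = 1.53e-07), and Ccl5 10600 ± 656 against 364 ± 43.3. Tbx21 was higher by 4.91 ± 0.28, Fasl (3.47 ± 0.18), Cxcr3 (3.18 ± 0.21) and Nkg7 (4.04 ± 0.21) went the same way, and Socs2, an inhibitor of cytokine signalling, rose from 28.2 ± 3.18 to 1400 ± 162. Il10 (1.94 ± 0.17) and Pparg (1.33 ± 0.24) were higher in fat Tconv too. Lower were A530021J07Rik (-2.95 ± 0.27), Dapl1 (-1.92 ± 0.43), Ccr7 (-1.59 ± 0.36) and Snn (-2.36 ± 0.24).

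Helper subset regulators rose in 11 of 14 cases in fat Tconv, 13 adjusted over the list alone (median relative change 1.02; adjusted p = 2.33e-05, and 0.0297 with an estimated correlation), with Tbx21, Rora (3.32) and Eomes (1.76) among them. Effector cytokines rose in 14 of 19 cases, 14 adjusted over the list alone and 9 with quantile normalization, which put 1 lower (adjusted p = 0.000986, and 0.0457 with an estimated correlation). The markers of NK cells and cytotoxic cells rose in 9 of 12 cases, 9 adjusted over the list alone, and 5 rose and 2 fell with quantile normalization (adjusted p = 0.0158, but 0.0786 with an estimated correlation). Chemokines and their receptors rose in 21 and fell in 1 of 30, 21 and 1 adjusted over the list alone (adjusted p = 2.33e-05, but 0.13 with an estimated correlation), with Cxcl2 (5.47), Ccl5 (4.53) and Cxcr4 (4.16) higher. The activation and tissue residence list rose in 22 of 26 genes, 23 adjusted over the list alone (median 1.73; adjusted p = 7.71e-12, and 0.00251 with an estimated correlation). The naive list fell in 9 and rose in 1 of 14, 9 and 1 adjusted over the list alone (median -1.35; adjusted p = 7.96e-10, and 0.0207 with an estimated correlation). Cell division genes rose in 16 of 27 cases, 17 adjusted over the list alone, among them Mki67 (1.99) and Cdk1 (1.67), and in 7 with quantile normalization (adjusted p = 0.0937). Glycolysis genes rose in 7 of 12 cases, 7 adjusted over the list alone (adjusted p = 0.0745), where 4899 of all 12821 genes rose as deposited. The adipose Treg list was higher in 19 of 21 genes, 20 adjusted over the list alone and 16 with quantile normalization (median 1.85; adjusted p = 7.96e-10, and 0.00555 with an estimated correlation). Treg identity genes were 15 higher and 2 lower of 25, 15 and 2 adjusted over the list alone (adjusted p = 0.0124, but 0.371 with an estimated correlation), sterol synthesis genes higher in 13 of 16, 13 adjusted over the list alone and 7 with quantile normalization (adjusted p = 0.0124, but 0.249 with an estimated correlation), and type I interferon genes 3 higher and 4 lower of 21, 3 and 4 adjusted over the list alone (median -0.41; adjusted p = 0.000658, but 0.339 with an estimated correlation).

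The fat tissue and stress transcripts moved in Tconv as well. Stress genes rose in 28 of 30 cases, 28 adjusted over the list alone (median 2.94; adjusted p = 3.12e-18, and 0.00555 with an estimated correlation), with Hspa1a (8.20 ± 0.26), Hspa1b (6.77 ± 0.54) and Klf4 (5.56 ± 0.35) among them. Stromal markers rose in 10 of 11 cases, 10 adjusted over the list alone (median 1.40; adjusted p = 2.54e-05, but 0.249 with an estimated correlation). Macrophage markers rose in 14 of 19, 15 adjusted over the list alone (median 0.73; adjusted p = 0.02, but 0.569 with an estimated correlation), and adipocyte markers in 6 of 8, 6 adjusted over the list alone (adjusted p = 0.00359, but 0.249 with an estimated correlation). With quantile normalization these counts were 8, 7 and 3. Fabp4 measured 2310 ± 631 in fat Tconv and 7.3 in lymph node Tconv. Reference genes rose in 6 of 13 cases as deposited, 6 adjusted over the list alone, with a median relative change of 0.04 (adjusted p = 0.837).

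In Tconv 5425 genes passed as deposited, 4899 higher and 526 lower in fat, and 1174 and 526 passed in 1 direction under the 3 scales, 616 and 160 of them at least 2-fold. With replicate number as a block 5478 passed. Within runs 3, 4 and 5 the median relative change was 1.46, 1.06 and 0.97 for helper subset regulators, 0.75, 0.52 and 0.51 for effector cytokines, 3.15, 2.75 and 2.29 for the stress list, 1.52, 0.98 and 2.08 for stromal markers and 1.43, 0.27 and 0.91 for macrophage markers. Between the 2 cell types, 804 of the genes higher under the 3 scales and 400 of those lower were shared, where independent lists would give 150 and 48.3. These lists are not independent, as they share one spread per gene, and Treg and Tconv arrays of a number varied together.

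Whether the Treg effect itself differed between fat and lymph node was tested as a difference of the 2 Treg effects, in which tissue differences common to both cell types cancel. On the side of fat Treg lay the chemokine gene Cxcl3 (6.81 ± 0.26), AA467197 (6.06 ± 0.37), Hpgd (4.49 ± 0.42), Ccr1 (3.97 ± 0.32), Il10 (3.54 ± 0.23) and Pparg (3.46 ± 0.34). Of these, Cxcl3, AA467197, Hpgd, Ccr1 and Pparg lay below the dim filter in both lymph node groups, with a mean of at most 27.2. Their Treg effect there is poorly measured, so the size of the difference is approximate; Tbx21 likewise measured 50.6 and 35.1. Among the genes with a lower Treg effect in fat were Ifng (-5.54 ± 0.68), Tbx21 (-5.13 ± 0.40), Cxcr3 (-4.85 ± 0.30), Fasl (-4.43 ± 0.25) and Ccl5 (-3.50 ± 0.35). Socs2 (-4.61 ± 0.36) measured 541 ± 127 in Treg against 28.2 ± 3.18 in Tconv of lymph node, and 1080 ± 79.6 against 1400 ± 162 in fat. Other Socs2 probe sets gave differences from -4.74 to -0.09. Foxp3 (-0.19 ± 0.39, adjusted p = 0.903) and Ctla4 (-0.90 ± 0.46, adjusted p = 0.406) did not pass the test of a difference.

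The adipose Treg list, partly chosen on these arrays, had a higher Treg effect in fat in 9 genes and a lower one in 1 of 21, the same adjusted over the list alone (median 0.73; adjusted p = 1.73e-09, and 0.0128 with an estimated correlation). In the Treg identity list 10 of 25 genes had a lower effect in fat and 1 a higher one, with 13 and 2 adjusted over the list alone (median -0.90; adjusted p = 2.13e-09, but 0.18 with an estimated correlation). Klrg1 (-1.88 ± 0.28) and Tnfrsf9 (1.42 ± 0.37) are a gene of each kind. Cell division genes had a lower effect in 3 of 27 cases, 7 adjusted over the list alone (median -1.04; adjusted p = 6.07e-07, but 0.592 with an estimated correlation). Type I interferon genes had one in 3 of 21, 6 adjusted over the list alone (median -0.45; adjusted p = 0.00383, but 0.592 with an estimated correlation). Macrophage and monocyte markers had a median difference of 0.49 (adjusted p = 0.0505, but 0.000585 with the replicate block). Stromal, endothelial and mesothelial markers had one of 0.40 (adjusted p = 0.183, but 0.00835 with the replicate block). No estimated correlation was used with the block. Unequal shares of other cells in the 2 fat sorts would not cancel in this difference. In all 622 genes passed, 277 with a higher and 345 with a lower Treg effect in fat, and 1416 with the replicate block (599 and 817). Within runs 3, 4 and 5 the median difference was 0.54, 0.99 and 1.35 for the adipose Treg list and -1.65, -1.09 and -0.22 for the Treg identity list.

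**Figure D4:**
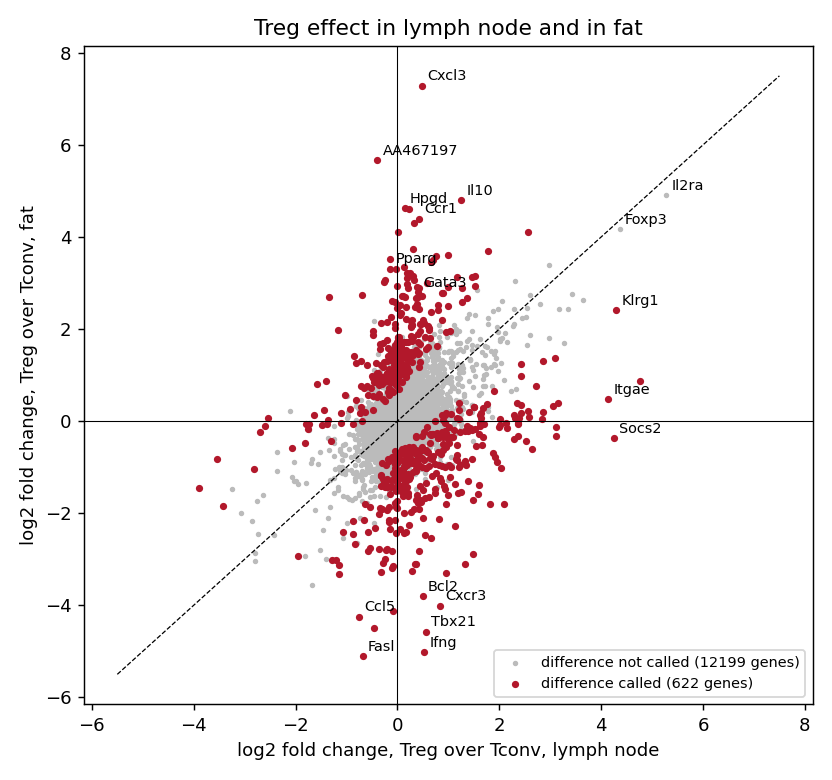
Treg effect in lymph node (x axis) against Treg effect in fat (y axis), both as log2 fold change of Treg over Tconv; each point is 1 of 12821 genes. The 622 genes whose effects differed by the test of the difference are coloured, and the other genes are grey.

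The difference of Treg effects between thymus and lymph node was tested in the same way; strain, age, sex and tissue cannot be told apart in it, as Xist measured 3280 in thymic and 40.2 in lymph node Treg and the Y-linked Eif2s3y 7.89 and 2070. The Treg effect was higher in thymus for S100a6 (3.59 ± 0.48) and S100a4 (2.45 ± 0.46), both calcium-binding protein genes, Eomes (2.97 ± 0.41), a T-box factor, Il18r1 (2.84 ± 0.33), the interleukin-18 receptor gene, and Ccl5 (2.30 ± 0.35). It was lower for Naip5 (-2.75 ± 0.42), Prg4 (-2.51 ± 0.28), Irf4 (-2.09 ± 0.36) and Cxcl2 (-1.97 ± 0.31); Naip5, Prg4 and Cxcl2 lay below the dim filter in both thymus groups, and Cxcl2 in both lymph node groups too, so these sizes are approximate. Of the markers of NK cells and cytotoxic cells, 2 of 12 had a higher effect in thymus, 4 adjusted over the list alone (median 0.38; adjusted p = 9.56e-06, and 0.00705 with an estimated correlation). Foxp3 (0.21 ± 0.39, adjusted p = 1) did not pass. Il10 (-1.13 ± 0.23) did not pass in the unpaired fit (adjusted p = 0.0513) and did with the replicate block (0.0071). By limma 39 genes passed, 20 higher and 19 lower, with 695 at an unadjusted p under 0.05 and 136 with the replicate block (52 and 84). Only run 3 holds both tissues, so values within runs cannot be compared; the count was 24 without thymus Tconv replicate 2, 25 without lymph node Tconv replicate 3 and 69 without thymus Treg replicate 3.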

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

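All tests of explanations in this part, and the regroupings of arrays, were chosen after the results were seen; the tests of the differences between tissues were planned. The Treg effect in fat differed from that in lymph node in 622 genes, by the test of the difference; values are differences in log2. It was higher in fat for the secreted factors and their receptors Cxcl3 (6.81), Ccr1 (3.97), Il10 (3.54), Il10ra (1.63) and Ccr9 (2.69), for the regulators Pparg (3.46), Gata3 (2.39), Tox2 (4.04) and Atf3 (2.79), and for AA467197 (6.06), Hpgd (4.49), Tmtc2 (4.39), 1700061F12Rik (4.11), Dmxl2 (3.98), Tnfrsf9 (1.42), Pdcd1 (2.52), Lgals3 (1.56) and H2-Eb1 (0.97). It was lower in fat for Ifng (-5.54), Tbx21 (-5.13), Cxcr3 (-4.85), Fasl (-4.43), Ccl5 (-3.50) and Nkg7 (-4.27). Lower too were Socs2 (-4.61), P2rx7 (-4.43), Gm8369 (-4.36), Bcl2 (-4.30), Klrg1 (-1.88), Bach2 (-2.95) and Itgb1 (-3.44), and Scd2 (-1.22), Hk2 (-2.03), Mki67 (-2.50), Egr2 (-1.76), Ifit2 (-1.61), Bank1 (-2.31) and Satb1 (-1.72). Cxcl3, Ccr1, Pparg, Atf3, AA467197, Hpgd, 1700061F12Rik, Dmxl2, Lgals3 and Tbx21 lay below the dim filter in both lymph node groups, so the size of their difference is approximate. By list, the median difference was -0.90 for Treg identity (adjusted p = 0.18 with an estimated correlation), -1.04 for cell division (0.592), -0.45 for the type I interferon response (0.592) and 0.73 for adipose Treg genes (0.0128). Macrophage (0.49) and stromal markers (0.40) passed camera at the preset correlation with the replicate block (adjusted p = 0.000585 and 0.00835) and not in the unpaired fit.

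Between thymus and lymph node the Treg effect differed in 39 genes. It was higher in thymus for S100a6 (3.59), A530021J07Rik (3.36), Dapl1 (2.99), Eomes (2.97), Il18r1 (2.84), Pla2g4f (2.83), S100a4 (2.45), Ccl5 (2.30) and Fosl2 (1.74). It was lower for Naip5 (-2.75), Prg4 (-2.51), Gsta4 (-2.20), Irf4 (-2.09), Mtmr7 (-2.03), Hopx (-2.03), Cxcl2 (-1.97), Gbp2b (-1.96), Slc2a3 (-1.12) and Bank1 (-1.42). The size is approximate for Pla2g4f and Cxcl2, below the dim filter in both lymph node groups, and for A530021J07Rik, Dapl1, Naip5, Prg4, Gsta4, Mtmr7, Cxcl2 and Bank1, below it in both thymus groups. List medians of the difference were 0.26 for T cell activation (adjusted p = 0.35 with an estimated correlation and 0.0807 with the replicate block), 0.29 for sterol synthesis (0.35), -0.27 for adipose Treg genes (0.35) and 0.38 for NK and cytotoxic cell markers (0.00705).

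Regrouping the same arrays gave fewer calls than the real groups, in designs that allow few splits. Treg and Tconv arrays of a number varied together and share an array run, so they were kept as pairs. For the differences of Treg effects the residuals of a fit of tissue plus cell type were moved between tissues as whole pairs. That makes 10 splits, and a share is never under 0.1: the real one, 1 of the 10, gave 622 calls for fat and 39 for thymus, and the highest other 0 in both. Shuffling the residuals of single arrays, which breaks the pairs, gave at most 432 and 9 calls in the other 99 of 100 draws. Comparisons of 2 groups allow only 10 splits as well. The real split, 1 of the 10, gave 554 calls in lymph node (highest other 4), 638 in thymus (3), 1476 in fat (8), 7018 in Treg of fat against lymph node (0) and 5425 in Tconv (0). Within a tissue 4 of the 10 splits part every pair as the real one does, and the highest other of these gave 0 calls in each of the 3 tissues. All these other splits mix arrays, or residuals, of the real groups, so a real difference enters the spread within groups. Their low counts follow in part from that mixing and do not show what chance alone would call.

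Markers of other cells of fat tissue were higher in both fat groups although the sort took CD4+ TCRb+ and CD11b- cells. The higher scale of the fat arrays is argued against as the whole cause for the markers that still passed as higher in fat Treg after quantile normalization. These were 27 of the 36 stromal, adipocyte and macrophage markers above the dim filter on that scale (38 as deposited). The filter keeps a gene that is bright in any 1 group, and Fabp4, Dcn and C1qb passed it only through fat. Markers dim in every group are not counted, so 27 of 36 is no share of the whole lists. Deviations from the group means correlated across the 6 fat arrays at a mean of 0.740 among 11 stromal markers and 0.664 among 19 macrophage markers, both at percentile 100 of 10000 random lists of like brightness, which is consistent with stromal cells, macrophages or their RNA in the sorts, or with another factor shared by arrays of a run: Dcn was highest in the fat arrays of run 5 (5107 and 2943) and C1qb in those of run 3 (627 and 305). Whether adipocytes are the whole source of Fabp4 cannot be told apart from its expression in the T cells or in other cells of the sorts. Its SD within groups was 0.283 of the median SD of Car3 and Lpl (1.75-fold from lowest to highest fat array, against 7.87-fold and 7.08-fold). Only these 2 other markers above the dim filter rose enough to compare. Adipoq, below the filter, measured 86.8 ± 91.9 in fat Treg and 52.4 ± 35.2 in fat Tconv (SD, n = 3), against 13.6 and 14.8 in lymph node. Tissue, with mouse age, sort and cell isolation, stays untested as a biological source.

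Ifng, Ccl5, Tbx21, Fasl, Cxcr3 and Nkg7, chosen for the size of their change, were higher in fat Tconv than in lymph node Tconv. NK cells in the sort cannot be told apart from expression in the CD4 T cells, although the fat sort took TCRb+ cells. The 8 NK and cytotoxic cell markers above the dim filter, with Nkg7, Ccl5 and the CD8 genes left out, had a median change of 0.591 after quantile normalization. Its SE, 0.402, is taken over markers and not over arrays. Of the 8 markers, 6 lay above 0 and 2 below. Below the filter Ncr1 changed by 0.20, Klra8 by 0.20 and Klre1 by -0.56. Klrk1 and Tyrobp passed the filter only through fat, so the filter favours markers that rose and the median of 0.591 leans upward. Eomes measured 828 ± 300 in fat against 196 ± 76.9 in lymph node Tconv (SD, n = 3), Gzma 206 ± 73.3 against 80.9 ± 33.3, Klrk1 95.6 ± 13.9 against 50.8 ± 7.8 and Tyrobp 90.6 ± 17.2 against 30.6 ± 3.45, while Klrd1 measured 252 ± 105 against 403 ± 152 and Prf1 83.3 ± 4.16 against 90.2 ± 15.3. CD8 T cells cannot be told apart either: Cd8a and Cd8b1 changed by a mean of -0.110, the higher change plus 2 SE was 0.356, and the sort removed CD8a+ cells, but Cd8b1 lay below the dim filter in both groups (52.6 ± 2.27 against 48.2 ± 2.78). A larger share of effector cells among CD4 T cells of fat remains open as a biological explanation, together with mouse age and handling, none of which these arrays test.

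Il10, Pparg, Ccr1, Cxcl2 and Cxcl3 were higher in fat Treg than in fat Tconv by 3.31 to 7.28. More macrophages or their RNA in the Treg sort are argued against as the whole cause, as 19 macrophage markers had a median change of 0.401, under 3.31. More adipocytes are argued against likewise, with a median of 0.170 over 8 markers. The SEs of these medians, 0.176 and 0.165, are taken over markers and not over arrays. Markers vary together, so these SEs can understate the error between arrays. With the replicate block the macrophage list passed camera as higher in fat Treg (adjusted p = 0.00169, at the preset correlation only), so a smaller share of the change is not excluded. A difference of cell isolation between the 2 sorts also remains: of the immediate early and stress genes Atf3 (2.99), Gadd45b (1.82) and Fosb (1.77) were higher in fat Treg and Hspa1a (-1.22) lower. An unequal rise of single macrophage genes and a state of Treg in fat remain open too; the last is the biological explanation the design gives, as a hypothesis.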

How the results depend on the processing

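The fit without the fat arrays of run 5 and the count over 3 scales were chosen after the data were seen; all other alternatives were planned. Across the alternatives other than leaving out single arrays, 100 counts stayed within 1.5 times the main count and 58 did not. In fat against lymph node, higher genes outnumbered lower ones as deposited but not after quantile normalization (4329 genes in Treg, 2860 in Tconv) or with centred arrays (4405 and 2578), both of which remove the shift of the fat arrays. On all 3 scales 2819 and 1700 passed. Requiring a 2-fold change left 329 genes in lymph node, 340 in thymus, 748 in fat, 1871 for Treg and 1310 for Tconv of fat against lymph node, and overlaps of 145 (lymph node and fat), 179 (lymph node and thymus) and 84 (3 tissues). A 2-fold difference of averages without a test gave 366 in lymph node, 803 in fat, 1885 and 1341 for fat against lymph node, 215 for the thymus difference, and overlaps of 157 (lymph node and fat) and 93 (3 tissues). The replicate block gave 1028 in lymph node, 1528 in thymus, 2652 in fat, 1416 and 136 for the differences of Treg effects in fat and thymus, and overlaps of 470, 584 and 299. Array run as a fixed block gave 876 in lymph node, 1209 in thymus, 1090 and 82 for the differences and overlaps of 408, 491 and 254; as a random block it gave 871, 1168, 1084, 94 and 403, 483, 249. The cause of these higher counts was not tested. Of the lists not called in the report, the replicate block added macrophage markers in Treg against Tconv of fat (camera adjusted p = 0.00169, preset correlation). For the fat difference it added macrophage markers (0.000585) and stromal markers (0.00835). It also added naive and lymphoid homing for the thymus difference (0.0387) and lipid genes in Treg of fat against lymph node (0.0433). In fat against lymph node Treg, where replicate numbers are no pairs, Slc4a1 lost its call with the block (adjusted p = 0.0464 and 0.0545). With only the compared groups in the fit 383 genes passed in thymus, with fewer arrays to estimate the spread. Testing genes without the dim filter gave 10837 and 8147 for Treg and Tconv of fat against lymph node, and testing every probe set gave 2358 in fat, 11632 and 9264 for fat against lymph node and 958 for the fat difference, since more features are counted. Array weights gave 2449 in lymph node, 3761 in fat, 9160 in Tconv of fat against lymph node, 3667 and 210 for the differences and overlaps of 712, 569 and 285; their fit stopped before its tolerance was reached, with weights from 0.284 to 6.50, so these counts are not relied on, and the cause was not tested.

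Leaving out each array in turn gave 388 to 464 genes in lymph node, 437 to 976 in thymus, 1104 to 1593 in fat, 5884 to 6965 and 4125 to 5233 for Treg and Tconv of fat against lymph node, 468 to 766 for the fat difference and 24 to 69 for the thymus difference. Overlaps ranged over 181 to 243 for lymph node and fat, 228 to 286 for lymph node and thymus and 121 to 146 for 3 tissues. The highest thymus counts, 976 and 69, came without thymus Treg replicate 3; without lymph node Tconv replicate 3 the thymus difference was 25. Without the fat arrays of run 5 the counts were 1225 in fat, 6253 and 4155 for fat against lymph node and 632 for the fat difference. With the mean of probe sets the sign of 3 named values turned: Sox4 (0.14) and Kdm5d (0.13), both in fat against lymph node Treg, and the fat difference of Ccr2 (1.00, which passed the test, against -0.02 on the probe set used). For Slc4a1 in fat against lymph node Treg the value became -0.016 both after quantile normalization and with centred arrays. Over the alternatives other than leaving out single arrays, 6815 values of named genes kept direction and side of the threshold, 200 lost the call, 78 gained one and 5 turned; for lists 2003 kept the call, 47 lost and 62 gained it. With single arrays left out 3728 gene values held, 384 lost and 10 gained the call, and for lists 1222, 30 and 44. Signals near background are compressed on these arrays, so changes of dim transcripts can be larger than measured, and differences of Treg effects that include them larger or smaller.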

Other observations

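Transcripts outside the main lists also marked the tissues. Alas2, the first enzyme of haem synthesis and a red cell gene, measured 579 ± 274 in fat Treg and 476 ± 94.9 in fat Tconv (SD, n = 3), against 30.7 ± 6.77 and 32.8 ± 6.91 in lymph node, relative changes of 3.80 ± 0.26 and 3.53 ± 0.26. The globin transcript Hba-a1 stayed below the filter in all groups, at 34.1 ± 3.74 in fat Treg and 21.5 ± 3.08 in lymph node Treg. Of the red cell transcripts, 2 of 2 passed as higher in fat Treg as deposited and 1 with quantile normalization, and with replicate number as a block Slc4a1 lost its call (adjusted p = 0.0545); in Tconv 1 of 2 did. Jchain, which links antibody subunits in plasma cells, was higher in fat Treg (1430 ± 876 against 161 ± 104; adjusted p = 0.00664). Gzma, a granzyme gene, measured 3710 ± 2580 in thymic Treg and 1120 ± 331 in thymic Tconv, against at most 206 ± 73.3 in the other groups. Gzma and Hba-a1 were chosen after their values were seen, and no test of them is given.

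Sex-linked transcripts set the thymus arrays apart. Xist, expressed from the inactive X chromosome of female cells, measured 3280 ± 198 in thymic Treg and 3420 ± 672 in thymic Tconv (SD, n = 3), against 40.2 ± 14.4 in lymph node Treg and 143 ± 18.2 in fat Treg. Eif2s3y, on the Y chromosome, measured 7.89 ± 0.587 in thymic Treg, 2070 ± 543 in lymph node Treg and 1440 ± 369 in fat Treg. Thymus and lymph node arrays thus differ in sex as well as in tissue. Uty, also on the Y chromosome, was higher in fat (521 ± 137 in Treg, 267 ± 52.7 in Tconv) than in lymph node (46.2 ± 16 and 43.6 ± 5.88). Between fat and lymph node 2 of 4 sex-linked genes were higher and 1 lower in Treg, the same adjusted over the list alone (adjusted p = 0.893). Markers of immature thymocytes were lower in lymph node Treg than in Tconv in 3 of 14 cases, 4 adjusted over the list alone, led by Themis (-1.96) and Satb1 (-1.29) (adjusted p = 0.0193, but 0.155 with an estimated correlation and 0.0575 with the replicate block); in thymus 2 fell, 3 adjusted over the list alone (adjusted p = 0.436).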
